A study of Mus musculus with 38 samples.

How the data were processed

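RNA sequencing was carried out on 4 macrophage populations sorted from the lungs of steady-state C57BL/6 mice aged 8 to 10 weeks. The interstitial populations were enriched for MerTK and sorted as live, CD64-positive and CD11b-positive cells without Siglec F, CD24, CD43 or Ly6G and without the lymphocyte markers CD3, B220 and NK1.1. They were then divided by surface MHC class II and CD206 (the mannose receptor) into IM1 (MHC class II low, CD206 high), IM2 (both high) and IM3 (MHC class II high, CD206 low). Alveolar macrophages (AM) were sorted separately as CD11c-positive, Siglec F-positive cells without CD11b, CD103 or Gr1 and without the same lymphocyte markers. Per the labels, RNA came from about 50000 cells, its integrity numbers lay between 9.2 and 10.0, and 2 ng entered a SMART-Seq v4 amplification followed by sequencing of pooled libraries on Ion Proton. Each population had 3 replicates (A, B and C). The 38 deposited samples are sequencing runs of these 12 libraries, with 3 runs per library and 5 for IM2 replicate A. Runs were summed to 1 value per library, since runs of 1 library are not replicates.

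The deposited gene values are counts per run, and per the file headers they came from featureCounts v1.5.0-p1 with unstranded counting on Ensembl 78 gene models, where reads mapping to several places or to several genes were not counted. A table of counts per replicate was also deposited, and its 43346 genes held the same values as the summed runs, with 0 cells differing. The deposited assignment summary holds counts of reads per assignment status and run, and the percentages of mapped reads given here were computed from it. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.5.1b and counted with Subread 1.5.0-p1, and DESeq2 1.8.1 under R 3.2.0 was named as well. Counting without strand means that a gene overlapped by another on the opposite strand, or a gene with close paralogs, can be over- or undercounted. Of the 43346 gene identifiers, 42462 (98.0%) had a symbol in the GENCODE M21 annotation, which also gave the mm10 coordinates, and 24692 genes had at least 1 count. The gene Gbp5 of the interferon list had no match and was left out.

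The libraries held between 11818981 and 15758326 assigned reads. A value of 0 therefore allowed up to 3 counts, which is 0.254 CPM (read counts scaled to library size) in the shallowest library and 0.19 in the deepest. A fold change against a group whose libraries all had 0 counts was taken against 3 counts over the whole group and is written as at least that fold. With 1 to 3 counts in a group the ratio of CPM is given with its 95% interval from the exact binomial distribution of the counts. These intervals and limits cover counting error only, since the reads were amplified and carry no molecular identifiers.

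Differential expression was tested with edgeR 4.0.16 under R 4.3.3 on raw counts, with TMM scaling, the filterByExpr filter by population (minimum count 10, which left 14095 genes), robust quasi-likelihood dispersion and the quasi-likelihood F test. All 12 libraries entered 1 fit with population as the only term, and p-values were adjusted by the Benjamini-Hochberg method over the 14095 genes of each comparison. This fit assumes the same spread in every population. Chi-square per degree of freedom, taken over genes between pairs of replicates, was 21.18 to 89.94 in IM1 and 15.93 to 25.75 in IM2. It was 13.37 to 17.09 in IM3 and 9.26 to 13.37 in AM. P-values for IM1 can therefore be too small, and those between IM2 and IM3 too large. A gene was called at an adjusted p under 0.05. The comparisons were the mean of the 3 interstitial populations against AM, each interstitial population against AM, and each pair of interstitial populations. Fold changes are log2 with their standard error (SE) from the same fit, and levels are TMM-scaled CPM with the standard deviation (SD) over libraries, except that the markers of other cell types are given as CPM of assigned reads without TMM factors. A gene was placed in a population's high or low set when it was called in the same direction against both other interstitial populations. The p-values measure the spread between these libraries only, because nothing in the labels says whether replicates A, B and C came from separate animals or separate pools.

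Gene lists were tested with camera in limma 3.58.1 on log2 CPM from voom with a preset correlation between genes of 0.01, two-sided, for the pooled interstitial populations against AM and for the 3 interstitial pairs. The 92 p-values from 23 lists and 4 comparisons were adjusted together. The lists were sort gate genes, alveolar macrophage markers, interstitial macrophage markers, CD206-high perivascular macrophage markers, MHC class II presentation, chemokines, cytokines, chemokine and cytokine receptors, growth factors and matrix remodelling, scavenger and phagocytic receptors, complement, pattern recognition, interferon response, lipid handling, fatty acid oxidation, cholesterol synthesis, glycolysis, lysosome, transcription factors, TGF-beta signalling, alternative activation, cell cycle, and dissociation and immediate early genes. Levels alone were read for markers of monocytes, dendritic cells, B cells, T cells, NK cells, neutrophils, eosinophils, mast cells and basophils, alveolar epithelium, airway epithelium, endothelium, fibroblasts and smooth muscle, mesothelium, erythroid cells and platelets, and for sex-linked genes. With camera's correlation estimated from the data, 13 of the 51 list calls remained. Principal components were taken on the 2000 most variable genes in log2 CPM with a prior count of 2.

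The comparisons, tests, thresholds, lists and the rule for naming genes were chosen before the data were examined. The rule took the sort gate genes; the 10 genes with the largest fold change in each direction between interstitial and alveolar macrophages; and the 8 in each direction between interstitial pairs. These genes had to be called, to reach 20 CPM in the higher group and to have every library of one side above every library of the other. The rule also took up to 6 genes of each population-specific set, up to 4 called members of each list with any member that was not called, and the most abundant marker of each other cell type. Predicted genes, pseudogenes and small RNA genes were left out of the ranked parts of the rule.

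The test was checked on simulated counts with the depth of these libraries. Apart from planted changes, each gene had the same mean and the same dispersion in all populations. The simulated IM1 libraries therefore varied no more than the others, unlike the real ones, and the check does not cover unequal spread. With no effect, 20 simulations gave a median of 0 called genes in each comparison and at most 2. With 200 changed genes planted between IM1 and IM2, edgeR found 57% of those changed 2-fold and 88% of those changed 4-fold, and called 8 unchanged genes. In the same data limma-voom found 58% and 86%, and DESeq2 1.42.0 found 68% and 89% with 28 unchanged genes called. In the camera check a planted list had p = 6.2e-59, and 3% of 200 random lists had p under 0.05.

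Labels did not say whether libraries with the same replicate letter shared mice or a sort. After population means were removed, the 3 same-letter pairs correlated across genes at 0.256, 0.166 and 0.292 between IM1 and IM2 and at 0.189, 0.143 and 0.163 between IM2 and IM3. Between IM1 and IM3 they correlated at 0.066, -0.122 and 0.165, and no pair with AM exceeded 0.1. The letters were therefore read as linking IM1 with IM2 and IM2 with IM3. Shared mice or sorts would link IM1 with IM3 as well, which these values do not settle, since pairs of unlike letters reached 0.156. The main fit leaves the letter out. Where the replicate letter as a block changed a result, its values are given beside that result or in the part on processing. Alternatives were RLE and upper-quartile scaling, no filter and a stricter filter on low counts, DESeq2, limma-voom, a fit of only the compared populations, replicate letter as a block, leaving out each library, only the run numbered 1 of each library, libraries thinned to the depth of the shallowest, the table of counts per replicate, and a 2-fold minimum. The further archive of processed values that the series description mentions was not analysed here. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.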

Results

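RNA was sequenced from 12 libraries of sorted mouse lung macrophages, 3 from each of 4 populations: alveolar macrophages (AM) and the interstitial populations IM1, IM2 and IM3. The series asks how the interstitial macrophages of the resting lung differ from each other and from alveolar macrophages. The AM libraries held 15304407, 15758326 and 14439177 assigned reads in replicates A, B and C. The IM1 libraries held 11818981, 13851387 and 14572622, and the IM2 libraries 12894548, 13640679 and 15652508. The IM3 libraries held 15020837, 13739160 and 14393658. Between 71.06% and 77.6% of mapped reads were assigned to genes. The interstitial libraries detected more genes, with 18451.33 ± 317.74 (SD, n = 3) in IM1, 18686.0 ± 224.03 in IM2 and 18397.0 ± 127.8 in IM3 against 16269.67 ± 212.86 in AM. The most abundant gene was Chil3, a chitinase-like protein, in AM, where it took 4.35% to 5.1% of reads. It was Cd74, the MHC class II invariant chain, in every IM2 and IM3 library, and Apoe or Lyz2 in IM1.

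Alveolar and interstitial macrophages were far apart in expression, and the 3 interstitial populations lay closer to each other. The main axis of variation held 87.2% of the variance over the 2000 most variable genes and placed AM at -165.03 to -163.34 and the interstitial libraries at 44.51 to 62.07, with IM3 at 44.51 to 48.68, IM1 at 54.49 to 56.83 and IM2 at 60.09 to 62.07. The next axis held 7.6% and placed IM1 at 26.94 to 37.74, IM2 at 5.91 to 16.53 and IM3 at -45.42 to -43.62. Across genes, the median correlation of log2 CPM between populations was 0.971 for IM1 and IM2, 0.96 for IM2 and IM3, 0.939 for IM1 and IM3, and 0.755 to 0.777 for AM against each interstitial population. Correlations between replicates were 0.989 to 0.99 in AM, 0.957 to 0.98 in IM1, 0.978 to 0.982 in IM2 and 0.982 to 0.983 in IM3, and genes are not independent replicates. IM1 replicate A stood apart from the other IM1 libraries: it was the shallowest library, had the highest shares of reads mapping to several places (14.78%) and from ribosomal protein genes (0.78%), and lay at -30.75 on the axis after these.

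**Figure D1:**
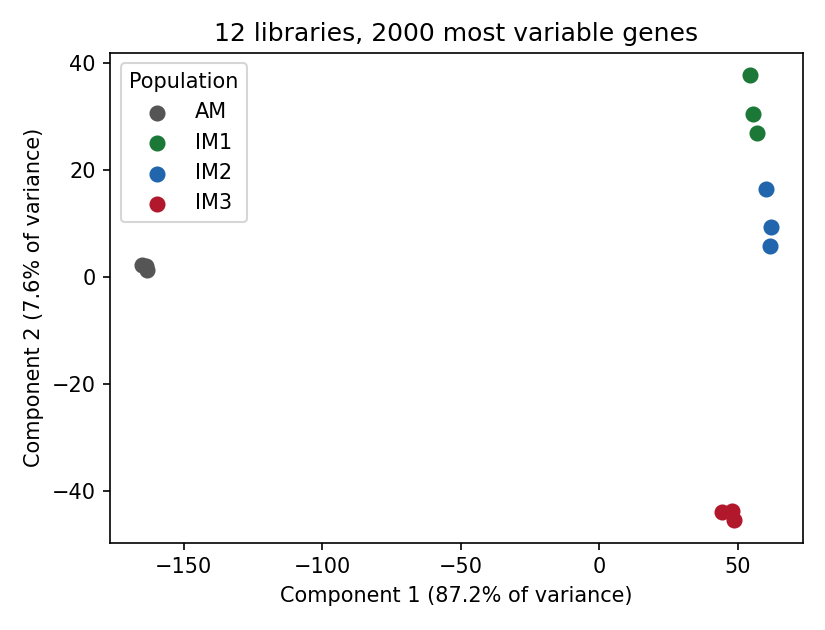
Principal components of the 12 libraries on the 2000 most variable genes, 1 point per library, with the share of variance on each axis. The AM libraries lie below -163 on component 1 and all 9 interstitial libraries above 44, and IM1, IM2 and IM3 separate along component 2.

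The question of what separates interstitial from alveolar macrophages was addressed by comparing the mean of the 3 interstitial populations (n = 9 libraries) with AM (n = 3). Interstitial macrophages carried the genes of complement component C1q, which starts the classical complement pathway, at levels that AM all but lacked. C1qc (ENSMUSG00000036896, mm10 chromosome 4, 136889804 to 136893065) reached 4676 ± 1433 CPM (SD) in interstitial libraries against a single count in all AM libraries, a ratio of 193000 (95% interval 34700 to 7640000). The ratios were 110000 (30400 to 907000) for C1qb (chromosome 4, 136880129 to 136886187) and 1e+05 (18000 to 3970000) for C1qa (chromosome 4, 136895917 to 136898803). In the other direction Chil3 (chromosome 3, 106147554 to 106167564) stood at 51280 ± 3306 CPM in AM and 86.94 ± 85.64 in interstitial macrophages, a log2 fold change of -9.98 ± 0.34 (SE) with adjusted p = 6.27e-13. Each of these genes had every interstitial library on one side of every AM library.

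The genes behind the sort followed the gates, which is no independent evidence since the cells were chosen on their products. Itgam, which encodes CD11b, was at 787.1 ± 110.8 CPM in interstitial macrophages and 9.725 ± 2.336 in AM (log2 fold change 6.33 ± 0.21, adjusted p = 5.08e-13). Siglecf was at 427.1 ± 19.28 CPM in AM and 1.871 ± 1.15 in interstitial macrophages (-8.01 ± 0.17, adjusted p = 4.43e-15), and Itgax, which encodes CD11c, was also higher in AM (-3.23 ± 0.17). Cd24a, whose product was gated out of the interstitial sort only, was higher in AM (-6.52 ± 0.21). Mrc1, which encodes CD206, was higher in interstitial macrophages by 0.61 ± 0.11, whereas Mertk, used for their enrichment, was higher in AM (-1.03 ± 0.11, adjusted p = 5.83e-07). Of the 14 gate genes tested, 7 were higher in interstitial macrophages and 6 in AM, the same numbers adjusted over the list alone, and Itgae had a value of -0.98 ± 0.52 (adjusted p = 0.113). Their median was 0.02, their mean was -0.08 and camera pointed up with adjusted p = 0.789.

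The genes with the largest differences had almost no reads on one side. Higher in interstitial macrophages by at least the stated fold, with 0 counts in all AM libraries, were Mmp9, a gelatinase (chromosome 2, 164940780 to 164955850, at least 13600-fold higher), Tmem176a (chromosome 6, 48841483 to 48845364, at least 10900-fold higher) and Fcrls, an Fc receptor-like gene (at least 10900-fold higher). Retnla, which encodes RELM-alpha, was at least 5950-fold higher, Ms4a4a at least 4450-fold and B3galnt1 at least 2780-fold. Tmem176b, the neighbour of Tmem176a, rose by 15.11 ± 0.34. Higher in AM were the lipase genes Lipf (chromosome 19, 33961187 to 33976810, at least 2610-fold higher, 0 counts in all interstitial libraries) and Ces2c, a carboxylesterase (at least 1550-fold), and the sodium-proton exchanger Slc9a2 (at least 1260-fold). Spag11b and Pnpla5 each had 1 count over the interstitial libraries, with ratios of 3830 (685 to 151000) and 2860 (512 to 113000). The keratin gene Krt79 had a log2 fold change of -10.87 ± 0.30, Trim29 -10.87 ± 0.29, and Rab44, Perp and Cpne5 lay between -10.61 and -10.57.

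Marker lists of the 2 kinds of macrophage separated without exception. All 24 alveolar macrophage markers tested were lower in interstitial macrophages, with a median log2 fold change of -7.79 (-7.52 with the genes at 0 counts at their bound) and camera adjusted p = 1.42e-20; Siglecf and Itgax among them were gated. All 18 interstitial macrophage markers were higher, with a median of 8.82 and adjusted p = 1.72e-11. Among these, Cx3cr1, the fractalkine receptor, stood at 645.1 CPM against 1.773 (8.49 ± 0.35). Apoe, which carries lipid out of macrophages, stood at 9809 CPM against 7.395 (10.22 ± 0.42). Of 18 CD206-high perivascular macrophage markers, 17 were higher in interstitial macrophages with a median of 10.07 (9.8 at the bound), and Colec12 had a value of 0.02 ± 0.13 (adjusted p = 0.913). Camera gave adjusted p = 5.62e-07 for this list, and adjusted p = 0.161 with an estimated correlation. Cd163, the haemoglobin scavenger receptor, was higher by 9.53 ± 0.18 and Stab1 by 10.11 ± 0.32. These counts were the same adjusted over the list alone.

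Complement, chemokine and receptor genes were more often higher than lower in interstitial macrophages, while their list calls ended with an estimated correlation. Among complement genes 13 of 17 were higher and 2 lower, with a median of 5.23 and camera adjusted p = 0.000177, and adjusted p = 0.125 with an estimated correlation. Serping1, the C1 inhibitor, was at least 320-fold higher, while Cr1l (0.22 ± 0.12, adjusted p = 0.128) and Cd59a (0.64 ± 0.37, adjusted p = 0.14) were not called. Among 22 chemokines 17 were higher and 3 lower, with a median of 4.34 and adjusted p = 0.00107, and adjusted p = 0.373 with an estimated correlation. Cxcl13, which attracts B cells, was at least 2090-fold higher and Cxcl12 at least 399-fold, and Ccl17 (0.01 ± 0.34, adjusted p = 0.99) and Cxcl9 (0.57 ± 0.37, adjusted p = 0.182) were not called. Cxcl12 stood at 23.58, 50.87 and 10.77 CPM in IM1, IM2 and IM3. The fibroblast marker Col3a1, also with 0 counts in AM, stood at 29.5, 44.2 and 34.7. Whether RNA of stromal cells gave part of the Cxcl12 and Serping1 levels was not tested. Among 23 chemokine and cytokine receptors 14 were higher and 5 lower (15 and 5 adjusted over the list alone), with a median of 1.67 and adjusted p = 0.0147, and adjusted p = 0.413 with an estimated correlation. Ccr2 rose by 4.63 ± 0.26. Cytokines went both ways, with 9 of 18 higher and 6 lower: Tnfsf9 rose by 6.64 ± 0.39, whereas Il1rn (-4.01 ± 0.12), Il18 (-3.70 ± 0.13) and Il1a (-2.90 ± 0.16) were higher in AM. The cytokine median was 0.45 and the mean 0.68, while camera pointed down with adjusted p = 0.931.

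For MHC class II presentation, 12 of 16 genes were higher in interstitial macrophages and 3 lower, with a median of 2.18 and adjusted p = 0.000778, and adjusted p = 0.192 with an estimated correlation. Since surface MHC class II defined the interstitial gates, the direction of this list is not independent evidence. The costimulatory genes Cd40 (6.81 ± 0.23) and Cd86 (adjusted p = 5.79e-12), which were not gated, were higher as well, and H2-DMb2 had a value of 0.09 ± 0.17 (adjusted p = 0.647). Of 25 interferon response genes 15 were higher and 3 lower (15 and 4 adjusted over the list alone), led by Ifitm3 (6.65 ± 0.43) and Oas2 (5.18 ± 0.28), with a median of 1.17 and adjusted p = 0.0147, and adjusted p = 0.435 with an estimated correlation. Pattern recognition genes were divided, 12 higher and 8 lower of 25, with a median of 0.42 and adjusted p = 0.645. Tlr12, a receptor for profilin of parasites, was at least 380-fold higher in interstitial macrophages and Tlr1 was higher by 7.15 ± 0.25. Scavenger and phagocytic receptors were also divided, 11 higher and 11 lower of 23. Marco, a bacterial scavenger receptor, stood at 416 CPM in AM and 1.875 in interstitial macrophages (-7.93 ± 0.23), opposite to Cd163. Their median was 0.02 and their mean 1.1, while camera pointed down with adjusted p = 0.758. Counts for which no other number is given were the same adjusted over the list alone.

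Most genes of 5 metabolic and lysosomal lists were higher in alveolar macrophages, and only the lipid list kept its call with an estimated correlation. Of 27 genes of lipid uptake, storage and efflux, 18 were lower in interstitial macrophages and 5 higher (18 and 6 adjusted over the list alone), with a median of -1.63 and adjusted p = 4.68e-05, and adjusted p = 0.016 with an estimated correlation. The lipid droplet gene Cidec (-9.65 ± 0.16), the fatty acid carrier Fabp4 (-7.71 ± 0.27) and the lipase Mgll (-6.38 ± 0.15) were among them, while Apoe went the other way. Of 25 genes of fatty acid oxidation 22 were lower and 0 higher at an adjusted p under 0.05, led by Acaa1b (-7.67 ± 0.19) and Acot1 (-2.77 ± 0.12), with a median of -1.26 and adjusted p = 4.96e-09, and adjusted p = 0.0531 with an estimated correlation. The 3 that were not called were Acadm (-0.12 ± 0.09), Decr1 (0.01 ± 0.12) and Fabp3 (1.16 ± 0.63). Of 22 genes of cholesterol synthesis 20 were lower (21 adjusted over the list alone), including Mvd (-2.98 ± 0.12) and Hmgcs1 (-2.57 ± 0.15), with a median of -1.46 and adjusted p = 3.56e-09, and adjusted p = 0.125 with an estimated correlation. Ebp (-0.33 ± 0.15) and Srebf2 (-0.09 ± 0.13) were not called. Of 18 glycolysis genes 14 were lower and 3 higher (15 and 3 adjusted over the list alone), with Aldoc (-4.86 ± 0.17) and Pkm (-1.67 ± 0.09) lower, a median of -0.84 and adjusted p = 0.000736, and adjusted p = 0.0673 with an estimated correlation. Of 27 lysosome genes 19 were lower and 3 higher (the same adjusted over the list alone), among them Ctsk, the matrix-degrading cathepsin K (-7.33 ± 0.21), and Ctsd (-3.81 ± 0.09). The lysosome list had a median of -0.7 and adjusted p = 0.000177, and adjusted p = 0.238 with an estimated correlation.

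All 31 cell cycle genes tested were lower in interstitial macrophages, with a median of -3.01, adjusted p = 7.56e-18, and adjusted p = 0.0295 with an estimated correlation. Rrm2, which makes deoxynucleotides, had a log2 fold change of -5.07 ± 0.13, Ccnb1 -4.81 ± 0.27 and Ube2c -4.13 ± 0.21. Dissociation and immediate early genes moved the opposite way, with 19 of 22 higher and 2 lower, a median of 3.34 and adjusted p = 8.85e-09, and adjusted p = 0.262 with an estimated correlation. Egr1 stood at 1214 CPM against 3.573 (8.39 ± 0.34), Socs3 rose by 5.49 ± 0.17 and Fosb by 5.32 ± 0.40, and Hspa1b had a value of 0.27 ± 0.17 (adjusted p = 0.184). The interstitial cells went through an additional enrichment and a different staining panel, so this difference is confounded with the sort. Of 22 TGF-beta signalling genes 16 were higher and 2 lower, led by Smad3 (6.29 ± 0.33) and the co-receptor Eng (4.52 ± 0.23), with a median of 1.21 and adjusted p = 0.00121, and adjusted p = 0.349 with an estimated correlation. Of 23 genes of growth factors and matrix remodelling 16 were higher and 6 lower, with a median of 4.21 (3.68 at the bound) and adjusted p = 0.0203, and adjusted p = 0.284 with an estimated correlation. Transcription factors were divided, 19 higher and 14 lower of 36, with a median of 0.45 and adjusted p = 0.611. Among them Runx3 (7.65 ± 0.45) and Klf2 (4.69 ± 0.20) were higher in interstitial macrophages. Alternative activation genes were divided as well, 7 higher and 6 lower of 15: Retnla was higher in interstitial macrophages and Chil3 in AM, and Arg1 (0.95 ± 0.46, adjusted p = 0.0795) and Ccl17 (0.01 ± 0.34) were not called. Their median was 0.48 and their mean 1.26, while camera pointed down with adjusted p = 0.789. The counts of these 6 lists were the same adjusted over the list alone.

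**Figure D2:**
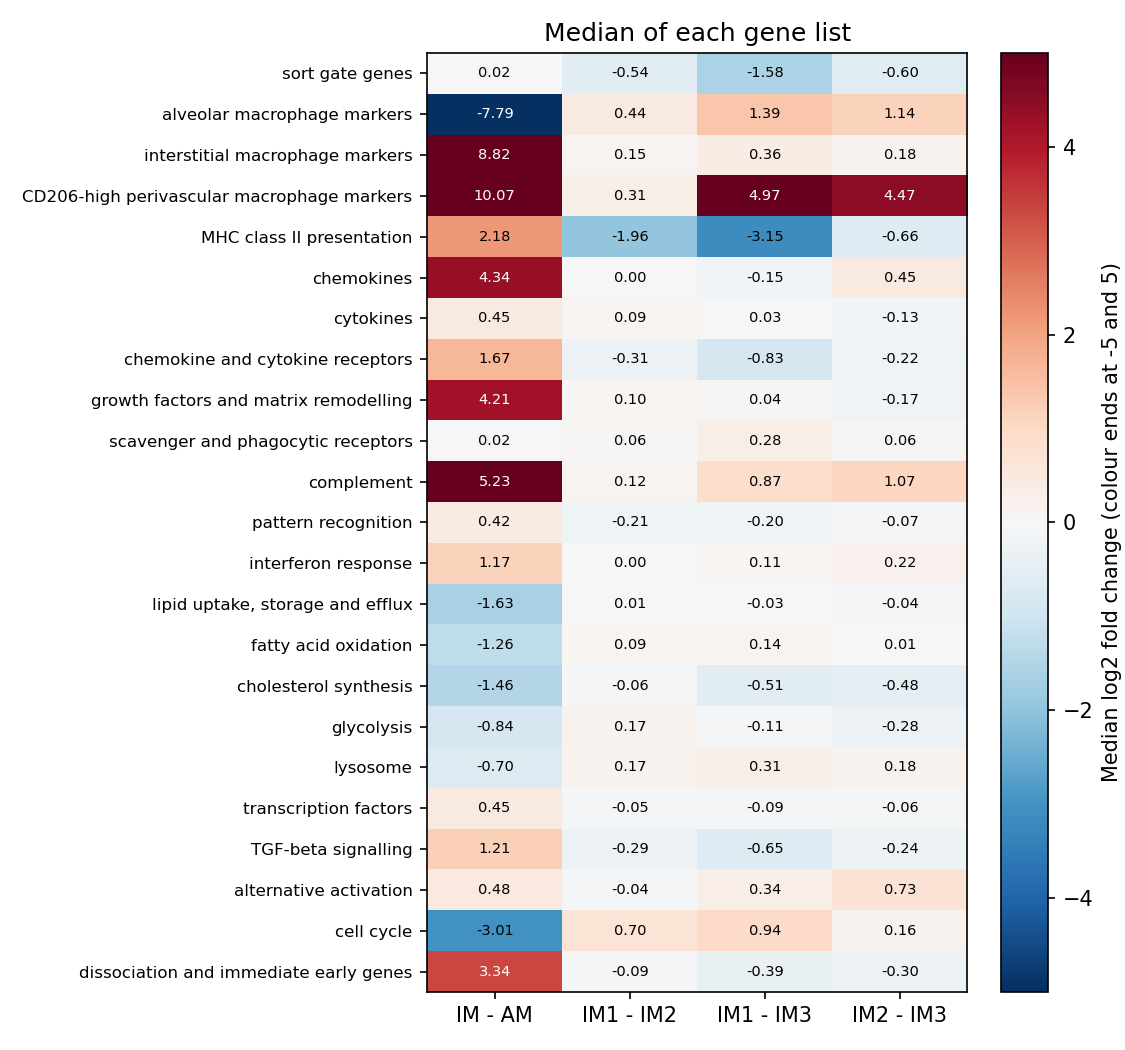
Median log2 fold change of the tested members of each of the 23 gene lists (vertical axis) in 4 comparisons (horizontal axis), as colours that end at -5 and 5. For interstitial against alveolar macrophages, alveolar macrophage markers have the lowest median (-7.79), and the CD206-high list (10.07) and interstitial macrophage markers (8.82) have the highest. The CD206-high list also stands out between IM3 and the other interstitial populations.

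With edgeR's quasi-likelihood test, 9107 of the 14095 genes were called between interstitial and alveolar macrophages, 5057 higher in interstitial macrophages and 4050 higher in AM, and 5224 of them differed at least 2-fold. The median log2 fold change of all genes tested was 0.1 here and 0.09 to 0.12 for the single populations against AM (0.12 to 0.18 with upper-quartile scaling), so small positive values are relative to that shift. Against AM, 8291 genes were called for IM1, 8529 for IM2 and 8094 for IM3. Of these, 3620 genes were higher and 2638 lower in each of the 3 populations, against 518.7 and 237.7 expected for independent lists. The 0 found in 20 simulations without effects in any comparison does not bear on genes that differ in only some populations. Part of the excess may come from the AM libraries that the comparisons share. The populations differed against AM in the gated genes: H2-Aa had a log2 fold change of 0.03 ± 0.17 (adjusted p = 0.908) in IM1, 3.92 ± 0.20 (adjusted p = 9.54e-11) in IM2 and 4.49 ± 0.20 (adjusted p = 3.4e-11) in IM3. Itgax was lower than in AM by -5.36 ± 0.28 in IM1, -3.33 ± 0.26 in IM2 and with adjusted p = 0.00189 in IM3. Mrc1 was higher than in AM in IM1 (1.10 ± 0.13) and IM2 (1.14 ± 0.13) and lower in IM3 (-0.42 ± 0.13, adjusted p = 0.0113), a call that ended without IM3 replicate A (adjusted p = 0.0549).

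Markers of several other cell types were higher in interstitial libraries than in AM, while those of others stayed low. All listed markers of NK cells (10), eosinophils (6), mast cells and basophils (7) and mesothelium (6) stayed under 10 CPM in every library, as did 10 of 11 T cell, 9 of 10 airway epithelium, 10 of 14 alveolar epithelium, 7 of 10 neutrophil, 7 of 10 B cell, 6 of 14 monocyte, 8 of 18 dendritic cell, 6 of 14 fibroblast and smooth muscle, 5 of 10 erythroid and platelet and 2 of 12 endothelial markers. The most abundant were Ccr2 for monocytes (mean CPM 12.8 in AM, 74.6 in IM1, 504 in IM2 and 1170 in IM3) and Siglech for dendritic cells (0, 364, 308 and 29.3 in the same order). For B cells it was Ighm (0.44, 923, 844 and 711), for T cells Il7r (0.196, 4.56, 9.75 and 33.9) and for neutrophils Csf3r (68.1, 75.6, 88.6 and 62.8). Abca3 led the alveolar epithelium list (96.4, 68.8, 96.4 and 83.7), Tppp3 the airway list (180, 247, 166 and 338), Inmt the fibroblast list (0, 143, 117 and 164), Lyve1 the endothelial list (0.0212, 665, 379 and 8.07) and Pf4 the platelet list (0.522, 693, 503 and 106). Lyve1 and Pf4 also belong to the macrophage lists. The collagen gene Col3a1 stood at 29.5, 44.2 and 34.7 CPM in IM1, IM2 and IM3 and had 0 counts in AM, and the beta-globin gene Hbb-bs at 224 CPM in AM and 9.06, 15.4 and 4.08 in the interstitial populations; both were chosen after their values were seen. Further stromal markers with 0 counts in AM, also chosen after their values were seen, were present in every interstitial population: Ramp2 at 17.5, 10.6 and 9.07 CPM, Col1a2 at 15.3, 22.4 and 20.6, and Bgn at 14.3, 15.2 and 16.6. The sex-linked gene Xist, expressed from the inactive X chromosome, stood at 52.8, 151, 159 and 120 CPM, higher in interstitial macrophages by 1.29 ± 0.22 (adjusted p = 7.84e-05). The 4 Y-linked genes had 0 to 3 counts each over all libraries (at most 0.139 CPM in any), as in female mice.

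**Figure D3:**
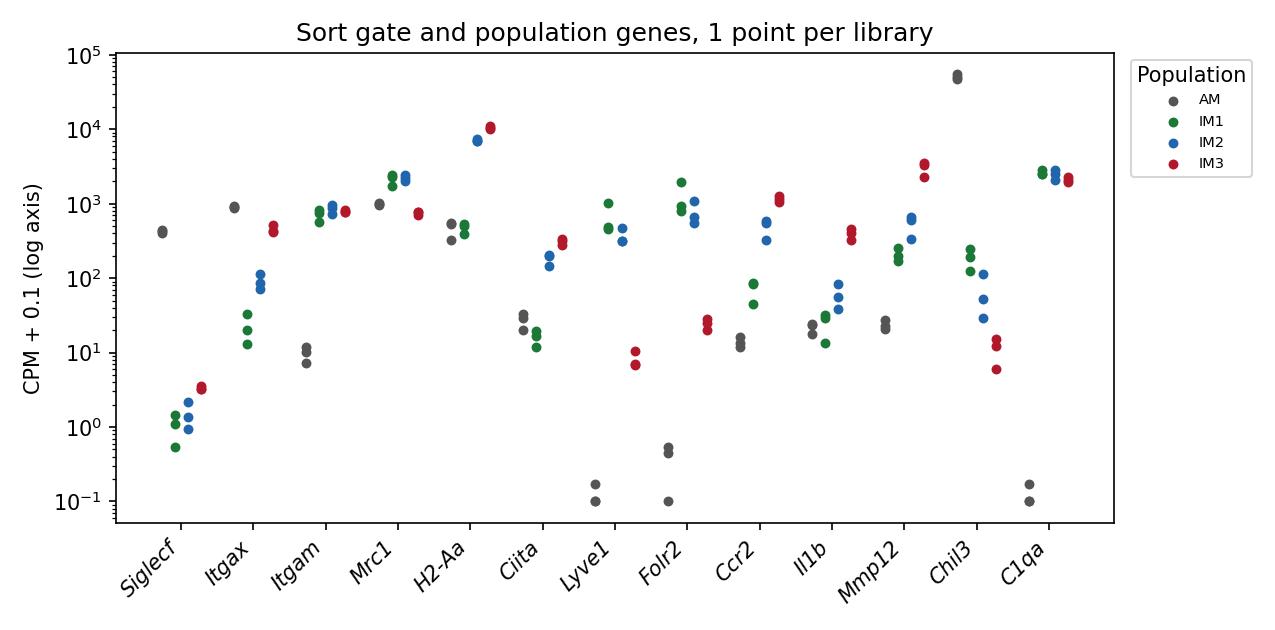
Levels of 13 sort gate and population genes as CPM + 0.1 on a log axis, 1 point per library, coloured by population. C1qa separates all 9 interstitial libraries from AM, the MHC class II genes H2-Aa and Ciita separate IM1 from IM2 and IM3, and Lyve1 and Folr2 separate IM3 from IM1 and IM2.

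IM1 and IM2 share high CD206 and differ in the MHC class II gate, and their comparison asked what else changes with it (n = 3 libraries each). IM2 carried the MHC class II genes at many times the level of IM1. H2-Eb1 (chromosome 17, 34305877 to 34316199) was at 240.7 ± 35.21 CPM in IM1 and 4828 ± 296.3 in IM2 (log2 fold change -4.33 ± 0.19, adjusted p = 2.58e-09). Ciita, the master regulator of MHC class II transcription (chromosome 16, 10488178 to 10527564), was at 15.79 ± 3.79 and 182.1 ± 31.55 CPM (-3.52 ± 0.21, adjusted p = 1.18e-07). IM2 also had more Ccr2, the monocyte chemokine receptor (chromosome 9, 124101950 to 124113557), at 489.2 ± 139.3 against 70.98 ± 22.84 CPM (-2.78 ± 0.25, adjusted p = 1.35e-05). IM1 had more Vsig4, a complement receptor of resident macrophages (chromosome X, 96247203 to 96293438), at 83.19 ± 21.64 against 16.8 ± 6.214 CPM (2.30 ± 0.28, adjusted p = 0.00041).

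Among the gate genes H2-Aa (-3.89 ± 0.20), H2-Ab1 (-3.82 ± 0.20), Cd74 (-3.53 ± 0.16) and Itgax (-2.03 ± 0.25, adjusted p = 0.000377) were lower in IM1 as well. No difference was detected for Mrc1 (-0.04 ± 0.13, adjusted p = 0.908), Mertk (-0.01 ± 0.14, adjusted p = 0.986) or Itgam (-0.27 ± 0.17, adjusted p = 0.424). Of 16 genes of MHC class II presentation 10 were lower in IM1 (11 adjusted over the list alone) and 0 higher, with a median of -1.96 and camera adjusted p = 1.42e-20, and adjusted p = 0.00866 with an estimated correlation; the gate makes this direction no independent evidence. H2-DMb1, a peptide-loading chaperone, fell by 2.30 ± 0.16 on the log2 scale, whereas Cd86 (0.13 ± 0.16, adjusted p = 0.683) and Cd40 (0.05 ± 0.16, adjusted p = 0.886) were not called. Mmp12, macrophage elastase, was also lower in IM1 (-1.38 ± 0.23, adjusted p = 0.00504). Of 23 chemokine and cytokine receptors 5 were lower in IM1 (9 adjusted over the list alone), with a median of -0.31 and adjusted p = 2.74e-07, and adjusted p = 0.125 with an estimated correlation. Higher in IM1 were Cd200r4 (1.49 ± 0.15, adjusted p = 5.3e-05), Gpnmb (1.26 ± 0.21, adjusted p = 0.00405) and the lysosomal proteases Ctsk (1.82 ± 0.29, adjusted p = 0.00319) and Ctsd (0.84 ± 0.12, adjusted p = 0.00125). The Ctsk and Ctsd calls ended in a fit of only the compared populations (adjusted p = 0.0612 and 0.0538). Ptprc, listed among the gate genes, had a value of -0.47 ± 0.13 (adjusted p = 0.0966). It was past the threshold with the replicate letter as a block (0.0319), with DESeq2 (0.0293), without the filter on low counts (0.0466) and without IM1 replicate B (0.0243).

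Of 31 cell cycle genes 8 were higher in IM1 and 0 lower (15 and 0 adjusted over the list alone), with a median of 0.7 and camera adjusted p = 4.34e-11, and adjusted p = 0.0793 with an estimated correlation. The cyclin gene Ccnb2 was at 22.9 ± 2.024 CPM in IM1 and 8.502 ± 0.8308 in IM2 (1.43 ± 0.15, adjusted p = 0.000108), and Stmn1 was higher by 1.05 ± 0.18, a call that ended in a fit of only the compared populations (adjusted p = 0.0616). Of 27 lysosome genes 4 were higher in IM1 (6 higher and 1 lower adjusted over the list alone), with a median of 0.17 and adjusted p = 0.000129, and adjusted p = 0.238 with an estimated correlation. Of 22 TGF-beta signalling genes 1 was lower in IM1 (7 adjusted over the list alone), with a median of -0.29 and adjusted p = 0.000204, and adjusted p = 0.289 with an estimated correlation. None of the 18 CD206-high perivascular macrophage markers was called by edgeR (4 were higher in IM1 adjusted over the list alone), with a median of 0.31 and camera adjusted p = 0.00215, and adjusted p = 0.348 with an estimated correlation. This list call ended without IM1 replicate A (adjusted p = 0.0608) and without IM2 replicate B (adjusted p = 0.0557). Lyve1 in that list had a value of 0.82 ± 0.27 (adjusted p = 0.153, 0.0226 without IM1 replicate B and 4.57e-05 without the filter on low counts) and Folr2 0.70 ± 0.33 (adjusted p = 0.29).

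Further lists past the threshold between IM1 and IM2 were the gate genes, pattern recognition genes and alveolar macrophage markers. Of 14 gate genes 5 were lower in IM1 and 0 higher (7 and 1 adjusted over the list alone), with a median of -0.54 and adjusted p = 4.34e-11, and adjusted p = 0.0113 with an estimated correlation. Of 25 pattern recognition genes 2 were lower (the same adjusted over the list alone), with a median of -0.21 and adjusted p = 0.00727, and adjusted p = 0.284 with an estimated correlation; this call ended without IM1 replicate A (0.0579). Of 24 alveolar macrophage markers 3 were higher in IM1 and 1 lower (6 and 2 adjusted over the list alone), with a median of 0.44 and adjusted p = 0.0244, and adjusted p = 0.292 with an estimated correlation. That call ended without IM1 replicate B (0.163), IM2 replicate B (0.0606) or IM2 replicate C (0.0805). Some of these markers were low in interstitial libraries, as Ctsk at 2.31% of its AM level in IM1 and 0.659% in IM2. Reads exchanged between pooled libraries may give part of such levels.

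In all, 241 genes were called between IM1 and IM2, 69 higher in IM1 and 172 in IM2, and 2472 genes had an unadjusted p under 0.05. With the replicate letter as a block the count was 392. With only IM1 and IM2 in the fit, which then took no estimate of the spread from AM and IM3, it was 71. The count of 241 depended on single libraries: it was 1904 without IM1 replicate B, 121 without IM1 replicate C, 110 without IM2 replicate B and 123 without IM2 replicate C. Without IM1 replicate A, which stood apart from the other IM1 libraries, it was 229. The median absolute log2 fold change was 0.25 with all libraries, 0.19 without IM1 replicate A and 0.35 without IM1 replicate B. The common dispersion was 0.0341, 0.0217 and 0.0285 in the same order. Called in the fit with all libraries and in every one of the 12 fits that left a library out were 86 genes, 20 higher in IM1 and 66 in IM2, a set chosen after the values were seen. It included H2-Aa, H2-Ab1, H2-Eb1, Cd74, Ciita, Ccr2, Itgax, Mmp12, Vsig4, Ctsk, Ctsd, Ccnb2, Cd200r4, Gpnmb and Stmn1, of which Ctsk (adjusted p = 0.0612), Ctsd (0.0538) and Stmn1 (0.0616) lost the call with only IM1 and IM2 in the fit.

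**Figure D4:**
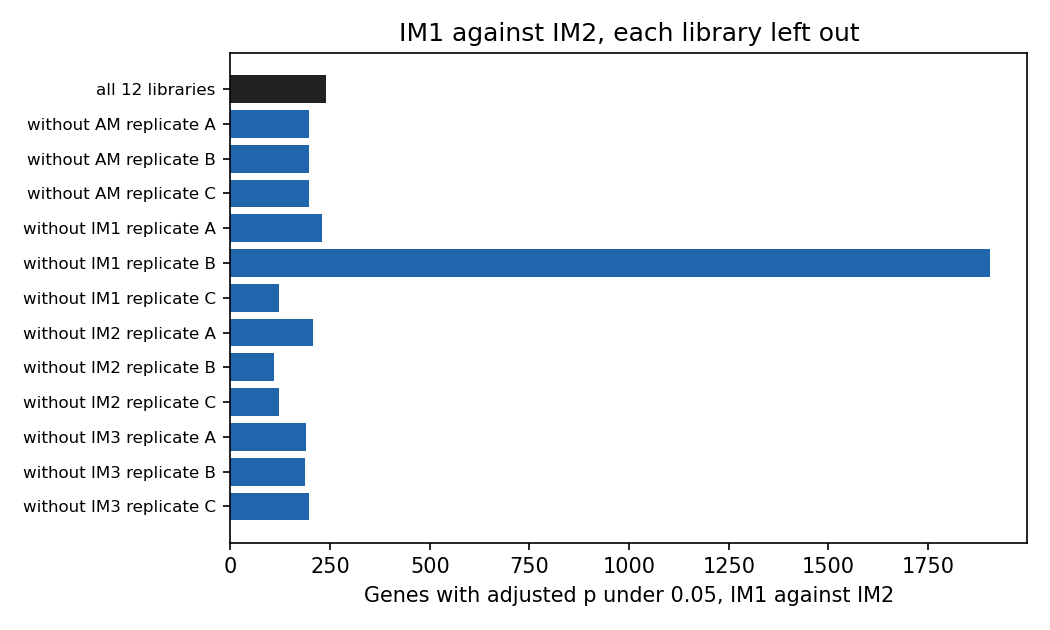
Number of genes with adjusted p under 0.05 between IM1 and IM2 (horizontal axis, from 0) with all 12 libraries (black bar) and with each library left out (blue bars). The count is 241 with all libraries and 1904 without IM1 replicate B.

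IM1 and IM3 are opposite in both gates, and their comparison gives the widest difference among the interstitial populations (n = 3 libraries each). IM1 carried most genes of CD206-high perivascular macrophages at higher levels than IM3. Lyve1, a hyaluronan receptor (chromosome 7, 110850607 to 110862953), was at 652.9 ± 313.4 CPM in IM1 and 8.019 ± 2.013 in IM3 (log2 fold change 6.35 ± 0.35, adjusted p = 5.86e-09). Folr2, a folate receptor, was at 1242 ± 644.7 and 24.22 ± 4.057 CPM (5.68 ± 0.41, adjusted p = 7.56e-08). IM3 carried more of the inflammatory cytokine Il1b (chromosome 2, 129364570 to 129371139), at 392.4 ± 66.64 against 24.88 ± 9.951 CPM (-3.97 ± 0.32, adjusted p = 2.5e-07), and more Ccr2 (-4.02 ± 0.26, adjusted p = 3.37e-08).

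The largest differences toward IM1 were in C-type lectin genes of the Cd209 family, with Cd209f (chromosome 8, 4102787 to 4105835) at 293.5 ± 126.3 against 1.862 ± 0.08909 CPM (7.29 ± 0.36) and Cd209g at 6.95 ± 0.42. Vsig4 (6.80 ± 0.39), the endothelin receptor Ednrb (6.63 ± 0.31) and the complement regulator Cd55 (5.78 ± 0.37) followed. The largest differences toward IM3 were in Klrb1b, a lectin of the NK receptor family (chromosome 6, 128813706 to 128826331), at 146 ± 14.86 against 1.872 ± 0.1324 CPM (-6.27 ± 0.27, adjusted p = 6.28e-10), and in the adhesion receptors Adgrg5 (-6.22 ± 0.36) and Adgrl3 (-5.87 ± 0.37). The matrix proteases were divided: Mmp13 (-5.03 ± 0.41) and Mmp12 (-3.88 ± 0.26) were higher in IM3, and Mmp9 (4.62 ± 0.19) in IM1.

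Of 18 CD206-high perivascular macrophage markers 17 were higher in IM1, with a median of 4.97 and camera adjusted p = 1.39e-24, and adjusted p = 0.016 with an estimated correlation. Mgl2 had a value of -0.02 ± 0.22 (adjusted p = 0.966). Mrc1, the gate gene of this list, was higher by 1.53 ± 0.13 (adjusted p = 5.58e-07), and the gate makes the direction no independent evidence. Of 16 genes of MHC class II presentation 11 were lower in IM1 and 1 higher, with a median of -3.15 and adjusted p = 1.82e-11, and adjusted p = 0.0222 with an estimated correlation. H2-Eb1 had a log2 fold change of -4.97 ± 0.19, and Cd40, the 1 gene higher in IM1, of 1.20 ± 0.16. Of 17 complement genes 11 were higher in IM1 and 0 lower, including C4b (5.25 ± 0.25) and properdin, Cfp (3.03 ± 0.20), with a median of 0.87 and adjusted p = 3.59e-08, and adjusted p = 0.035 with an estimated correlation. For these 3 lists the counts were the same adjusted over the list alone. Chemokines were divided, 10 higher and 9 lower of 22 (10 and 10 adjusted over the list alone), with a median of -0.15, a mean of 0.45 and adjusted p = 0.454. Ccl24 (5.51 ± 0.37) and Ccl8 (5.42 ± 0.42), which attract eosinophils and monocytes, were higher in IM1. The anti-inflammatory cytokine gene Il10 was higher in IM1 by 2.74 ± 0.40 (adjusted p = 0.000195).

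Of 31 cell cycle genes 18 were higher in IM1 and 0 lower (20 and 0 adjusted over the list alone), with Ccnb2 at 2.22 ± 0.16, a list median of 0.94 and adjusted p = 1.46e-07, and adjusted p = 0.141 with an estimated correlation. Of 23 chemokine and cytokine receptors 12 were lower in IM1 and 2 higher (13 and 2 adjusted over the list alone), including Tgfbr1 (-2.00 ± 0.18), with a median of -0.83 and adjusted p = 6.14e-06, and adjusted p = 0.161 with an estimated correlation. Of 22 TGF-beta signalling genes 11 were lower and 1 higher (the same adjusted over the list alone), with a median of -0.65 and adjusted p = 0.000151, and adjusted p = 0.284 with an estimated correlation. Of 22 genes of cholesterol synthesis 11 were lower (13 adjusted over the list alone), with a median of -0.51 and adjusted p = 0.000326, and adjusted p = 0.292 with an estimated correlation. Among alveolar macrophage markers 12 of 24 were higher in IM1 and 5 lower (13 and 5 adjusted over the list alone), with a median of 1.39 and adjusted p = 0.0509. This list was past the threshold without AM replicate A (adjusted p = 0.0474), IM1 replicate C (0.0182), IM2 replicate A (0.0297) or IM2 replicate B (0.0459). Chil3 (4.07 ± 0.44) and Ctsk (3.86 ± 0.34) were higher in IM1, while Itgax (-4.36 ± 0.27) and Pparg (-1.72 ± 0.17), a nuclear receptor of alveolar macrophages, were higher in IM3. Chil3 was at 0.361% of its AM level in IM1 and 0.0214% in IM3, and Ctsk at 2.31% and 0.158%. Reads exchanged between pooled libraries may give part of such low levels and cannot be told apart from low expression. In all, 3445 genes were called between IM1 and IM3, 1790 higher in IM1 and 1655 in IM3. With only IM1 and IM3 in the fit the count was 2268, and 1971 genes were called with all libraries and with each library left out.

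Dissociation and immediate early genes were more often lower in IM1 than higher, 8 against 1 of 22 (9 and 1 adjusted over the list alone), with a median of -0.39 and adjusted p = 0.000446, and adjusted p = 0.442 with an estimated correlation. The heat shock genes Hspa1b (-1.34 ± 0.21) and Hspa1a (-1.21 ± 0.18) and the stress factor Atf3 (-1.02 ± 0.19) were among them. Of 27 lysosome genes 13 were higher in IM1 and 3 lower, with a median of 0.31 and adjusted p = 0.00107, and adjusted p = 0.288 with an estimated correlation. Of 15 alternative activation genes 6 were higher and 4 lower, with a median of 0.34 and adjusted p = 0.0214, and adjusted p = 0.125 with an estimated correlation. Of 14 gate genes 3 were higher and 8 lower, with a median of -1.58 and adjusted p = 1.5e-05, and adjusted p = 0.0425 with an estimated correlation. The counts of these last 3 lists were the same adjusted over the list alone. Of 18 interstitial macrophage markers 6 were higher and 2 lower (8 and 2 adjusted over the list alone), with a median of 0.36 and adjusted p = 0.0452, and adjusted p = 0.238 with an estimated correlation. That call ended without IM1 replicate C (0.0608), IM2 replicate C (0.0532) or IM3 replicate B (0.0575).

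IM2 and IM3 share high MHC class II and differ in the CD206 gate (n = 3 libraries each). IM2 carried CD206-high genes at many times the level of IM3. Lyve1 was at 368.5 ± 93.97 CPM in IM2 against 8.019 ± 2.013 in IM3 (log2 fold change 5.52 ± 0.33, adjusted p = 4.15e-08), and Cd209f at 267.7 ± 75.32 against 1.862 ± 0.08909 (7.16 ± 0.36, adjusted p = 4.12e-08). The complement gene C4b (chromosome 17, 34728380 to 34743882) was at 1119 ± 82.08 against 24.63 ± 7.312 CPM (5.51 ± 0.25, adjusted p = 2.49e-09). IM3 had more Il1b (-2.72 ± 0.30, adjusted p = 1.36e-05) and Mmp12 (-2.50 ± 0.24, adjusted p = 3.66e-06).

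Of 18 CD206-high perivascular macrophage markers 17 were higher in IM2, with a median of 4.47 and camera adjusted p = 2.57e-36, and adjusted p = 0.00866 with an estimated correlation; Mrc1, used for the gate, was higher by 1.56 ± 0.13, and Mgl2 had a value of 0.44 ± 0.22 (adjusted p = 0.264). Of 17 complement genes 9 were higher in IM2 and 0 lower (10 and 0 adjusted over the list alone), with a median of 1.07 and adjusted p = 1.69e-09, and adjusted p = 0.0272 with an estimated correlation. C6, of the membrane attack complex (chromosome 15, 4727175 to 4815456), was higher by 5.73 ± 0.50. Of 15 alternative activation genes 5 were higher in IM2 and 1 lower (6 and 2 adjusted over the list alone), including Retnla (4.22 ± 0.37) and Clec10a (3.59 ± 0.30), with a median of 0.73 and adjusted p = 0.00019, and adjusted p = 0.0295 with an estimated correlation. The chemokine genes Ccl8 (5.53 ± 0.42) and Cxcl12 (2.24 ± 0.23) and the protease gene Mmp9 (5.03 ± 0.20) were higher in IM2. Higher in IM3 were Itgax (-2.33 ± 0.25, adjusted p = 9.27e-06), Klrb1b (-2.89 ± 0.21) and Ccr2 (-1.24 ± 0.24, adjusted p = 0.002).

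Although both populations were gated as MHC class II high, 11 of 16 genes of MHC class II presentation were lower in IM2 and 1 was higher (the same adjusted over the list alone), with a median of -0.66 and adjusted p = 1.04e-05, and adjusted p = 0.106 with an estimated correlation. Cd74 had a value of -0.70 ± 0.14 (adjusted p = 0.00317) and H2-DMb2 of -1.22 ± 0.19, while Cd40 was higher in IM2 by 1.14 ± 0.16. The call for H2-Ab1 (-0.70 ± 0.18, adjusted p = 0.0142) ended without IM2 replicate A (adjusted p = 0.073), IM2 replicate B (0.0522) or IM3 replicate B (0.0621). The call for H2-Eb1 (-0.64 ± 0.16, adjusted p = 0.0161) ended without IM2 replicate A (0.056), IM2 replicate B (0.073), IM3 replicate A (0.0647) or IM3 replicate B (0.0654). The call for H2-Aa (-0.57 ± 0.17, adjusted p = 0.0481) ended without AM replicate C (0.0549), IM1 replicate C (0.0543), IM2 replicate A, B or C (0.141, 0.137 and 0.109) or IM3 replicate A, B or C (0.116, 0.151 and 0.0984), and with upper-quartile scaling (0.0505). Of 23 chemokine and cytokine receptors 9 were lower in IM2 and 2 higher, with a median of -0.22 and adjusted p = 0.000852, and adjusted p = 0.284 with an estimated correlation. Of 22 genes of cholesterol synthesis 5 were lower (9 adjusted over the list alone), with a median of -0.48 and adjusted p = 2.75e-05, and adjusted p = 0.25 with an estimated correlation. In all, 1611 genes were called between IM2 and IM3, 915 higher in IM2 and 696 in IM3, and 945 were called with all libraries and with each library left out.

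Dissociation and immediate early genes were lower in IM2 for 4 of 22 and higher for 0 (the same adjusted over the list alone), with Hspa1b at -1.24 ± 0.21, a list median of -0.3 and adjusted p = 0.000703, and adjusted p = 0.456 with an estimated correlation; this call ended without IM3 replicate A (0.0578). Of 18 glycolysis genes 5 were lower and 2 higher (7 and 2 adjusted over the list alone), with a median of -0.28 and adjusted p = 0.00305, and adjusted p = 0.106 with an estimated correlation. Of 14 gate genes 8 were lower and 1 higher (8 and 2 adjusted over the list alone), with a median of -0.6 and adjusted p = 0.00554, and adjusted p = 0.161 with an estimated correlation. TGF-beta signalling had 4 lower and 1 higher of 22 (5 and 1 adjusted over the list alone; median -0.24, adjusted p = 0.013, and adjusted p = 0.442 with an estimated correlation). Chemokines had 9 higher and 6 lower of 22 (11 and 7 adjusted over the list alone), with a median of 0.45 and adjusted p = 0.0233, and adjusted p = 0.518 with an estimated correlation, and their call ended without IM3 replicate C (0.151). Lysosome genes had 7 higher and 3 lower of 27 (11 and 5 adjusted over the list alone), with a median of 0.18 and adjusted p = 0.0158, and adjusted p = 0.413 with an estimated correlation, and their call ended without IM2 replicate C (0.122). Cell cycle genes had 4 higher and 0 lower of 31 (5 and 0 adjusted over the list alone), with a median of 0.16 and adjusted p = 0.0203, and adjusted p = 0.442 with an estimated correlation, and their call ended without IM2 replicate B (0.0628) or C (0.0521).

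Genes that set 1 interstitial population apart from both others were few for IM2 and many for IM3. IM3 was high for 614 genes and low for 819, IM1 was high for 63 and low for 162, and IM2 was high for 8 and low for 5. With the replicate letter as a block these counts were 104 and 258 for IM1 and 13 and 10 for IM2. Independent lists would give 81.7 and 116.2 for IM3, 8.8 and 20.2 for IM1, and 11.2 and 3.4 for IM2, so the 8 IM2-high genes did not exceed that number. In 20 simulations without effects in any comparison each set held 0. These simulations do not give the number expected where 1 of the 2 comparisons has real differences. Part of any excess may come from the libraries that the paired comparisons share. The IM3-high genes included Klrb1b, Adgrg5, Adgrl3, Mmp13, Lrrc3 and Il1b, and the IM3-low genes Cd209f, Cd209g, Cd209d, Ednrb, Lyve1 and Ccl8. IM1 was high for Vsig4, Ctsk, Cd200r4 and Ccnb2 and low for H2-Eb1, H2-Aa, H2-Ab1, Cd74, Ciita and H2-M2. Cxcl12 was at 50.87 ± 10.21 CPM in IM2 against 23.58 ± 1.977 in IM1 and 10.77 ± 3.498 in IM3, and C1qtnf1 at 49.8 ± 5.775 against 23.9 ± 4.621 and 6.93 ± 2.186. The call between IM1 and IM2 ended without IM1 replicate C, IM2 replicate A or IM2 replicate C for Cxcl12 (adjusted p = 0.0642, 0.0669 and 0.107), and without IM1 replicate C, IM2 replicate B or IM2 replicate C for C1qtnf1 (0.0978, 0.0912 and 0.126). The 5 IM2-low genes were Spp1, Tuba4a, Plp2, Capg and the predicted gene 2010111I01Rik, the last named after its values were seen, and their IM1 against IM2 values were 0.92 ± 0.19, 0.81 ± 0.18, 0.89 ± 0.16, 0.54 ± 0.12 and 0.61 ± 0.14. Calls of these genes ended without single libraries. For IM1 against IM2, Spp1 lost the call without IM1 replicate C, IM2 replicate B or IM2 replicate C (adjusted p = 0.0589, 0.0616 and 0.107), Tuba4a without IM2 replicate A, B or C (0.109, 0.0744 and 0.114) and Plp2 without IM2 replicate B (0.0555). Capg lost it without AM replicate A, B or C (0.0541, 0.0542 and 0.056), IM1 replicate C (0.0804), IM2 replicate A, B or C (0.125, 0.109 and 0.0754), or IM3 replicate A or C (0.0587 and 0.056). For IM2 against IM3, Tuba4a lost it without IM2 replicate A (0.0584), and Plp2 without IM2 replicate A or B (0.0813 and 0.0527) or IM3 replicate A or B (0.0579 and 0.0814).

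Several of these counts depended on single libraries. The IM1-high count was 587 without IM1 replicate B, 30 without IM1 replicate C, 27 without IM2 replicate B and 29 without IM2 replicate C, and the IM1-low count was 1041, 86, 79 and 91 without the same libraries. The IM2-high count was 46 without IM1 replicate B, 5 without IM1 replicate C, 2 without IM2 replicate A, 4 without IM2 replicate B, 1 without IM2 replicate C, 4 without IM3 replicate A, and 3 without IM3 replicate B or C. The IM2-low count was 20 without IM1 replicate B and 0 without IM2 replicate B (edgeR). It was 2 without IM1 replicate C, IM2 replicate C or IM3 replicate A, and 3 without AM replicate B or IM3 replicate B or C.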

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

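The reads outside annotated exons were compared between populations only after their shares had been seen. The share of mapped reads outside annotated exons was 5.08% in AM (mean of 3 libraries), 9.55% in IM1, 11.12% in IM2 and 10.01% in IM3. AM libraries ranged from 3.89% to 6.31% and interstitial libraries from 8.6% to 12.39%, without overlap, with a difference of means of 5.15 and an exact permutation p of 0.0045, the smallest that 220 permutations can give. The reads themselves were not analysed here, and the difference is confounded with the different sorts of AM and interstitial cells.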

How the results depend on the processing

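The alternatives that leave out an IM1 library and change the tool were chosen after the counts were seen. Over 437 pairs of a named gene and a comparison and 23 alternatives, 9592 of 9919 values stayed on the same side of the threshold, whether called or not. Of the others 293 lost the call and 34 gained it, and 59 pairs lost it in at least 1 alternative. Where either fit made a call 0 reversed direction, and signs of uncalled pairs were not compared. The 437 values from the table of counts per replicate were the same by construction. Many pairs were named for large fold changes, so these shares do not hold for all calls. With each library left out, 86 of 241 calls between IM1 and IM2 and 1971 of 3445 between IM1 and IM3 remained. The count between IM1 and IM2 was 241 in edgeR. Without the filter on low counts it was 941, of which 929 were among the 14095 genes, and the IM1-high, IM1-low, IM2-high and IM2-low sets held 273, 532, 33 and 21 genes. The prior degrees of freedom were infinite in that fit and 7.25 with the filter. DESeq2 gave 591 genes and sets of 180, 339, 15 and 15. With the replicate letter as a block the values were 392 and 104, 258, 13 and 10, 8 of 12 libraries correlated best with their own letter, and of the calls of named genes and lists the block changed only those of Ptprc (adjusted p = 0.0319), Tppp3 (0.0443) and the complement list (0.0428) between IM1 and IM2 and of Tppp3 between interstitial macrophages and AM (0.0474), all gained. With only the compared populations in the fit, 71 genes differed between IM1 and IM2 and 2268 between IM1 and IM3, while the count between IM2 and IM3 rose from 1611 to 2143. The IM1-high, IM1-low and IM2-low sets then held 16, 49 and 0. That 0 came from edgeR fits of the compared populations alone, for which no other tool was run; in the edgeR fit of all 12 libraries 2472 genes had an unadjusted p under 0.05 between IM1 and IM2. With run 1 alone of each replicate the count was 155 and the IM1-high, IM2-high and IM2-low sets held 39, 3 and 2. Requiring also a 2-fold change left 5224 genes for interstitial against AM, 5222, 5333 and 5021 for IM1, IM2 and IM3 against AM, 1633 for IM1 against IM3 and 869 for IM2 against IM3. With an estimated correlation 13 list calls remained. Leaving out 1 library gave 110 (IM2 replicate B) to 1904 (IM1 replicate B) between IM1 and IM2, 27 to 587 for IM1-high, 79 to 1041 for IM1-low, 1 to 46 for IM2-high and 0 to 20 for IM2-low (edgeR). Without IM1 replicate A DESeq2 gave 393 genes, without IM1 replicate B limma-voom gave 1771 and DESeq2 2649, and without IM1 replicate C limma-voom gave 117. The cause was not tested.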

Other observations

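The tests of explanations in this part were chosen only after the results were seen, except the regrouping of libraries, which was planned, and the correlation of positions was added after the difference of -0.05 had been read as fitting a mixture. Of 682 genes that differed at least 2-fold between IM1 and IM3 with adjusted p under 0.05 and at least 20 CPM in either, 623 (91.3%) had an IM2 level between the others, at a median position of 0.25 (quartiles 0.15 and 0.39) for 354 genes higher in IM3 and 0.33 (0.11 and 0.49) for 328 lower in IM3, a median difference of -0.05 (-0.14 to 0.05 over 27 sets of 3 libraries). A sort of IM2 that mixed IM1 and IM3 cells would place all genes at one position, and differences between genes would not recur between sets that share no library. Outside the gated lists they recurred in part, with median correlations of 0.33 (-0.13 to 0.71) and 0.36 (-0.15 to 0.72) over 108 pairs of sets. Among the 682 genes, the 9 of the MHC class II list that were lower in IM1 lay further toward IM3 than the 672 outside that list. This held in every set (a difference of 0.29, 0.10 to 0.51). Cxcl12 at 50.87 CPM in IM2 lay above both IM1 (23.58) and IM3 (10.77) with a call that single libraries ended. These values do not decide, since the ranges of the correlations include 0, MHC class II was gated and Cxcl12 was picked from 8 IM2-high genes. A mixture and an intermediate state therefore cannot be told apart.

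The tests here were also chosen after the level of Ighm was seen, and Igkc, Cd79a and Ms4a1 after their own levels were seen. A form on the 8 other markers of the B cell list, Cd79a and Ms4a1 among them, gave 5.04% to 8.44% of Ighm (median 6.06%), which goes with B cells. Ighm (ENSMUSG00000076617, mm10 chromosome 12, 113418558 to 113422730) was at 826 ± 129 CPM (SD) over the 9 interstitial libraries, 663 to 1060, and 0.44 in AM. B cells would bring all their abundant transcripts, but Igkc was at 0.415, Cd79a at 0.696 and Ms4a1 at 0.595 mean CPM (Ms4a1 at 0.518 in AM), together at most 0.538% of the Ighm level, Pax5 had 0 counts in every library, and the gate removed cells with B220. Cd79b at 45.7 CPM (32.7 to 66.2) and Ighd at 6.08, both 0 in AM, moved with Ighm and made up most of the 6.06% that the 8 markers reached at the median. Reads of a neighbouring gene could be counted for it, but of 27 neighbours within 50 kb none reached more than 2.48% of the Ighm level in any library. The levels of Igkc, Cd79a, Ms4a1 and Pax5 go against B cells as the source, whereas Cd79b and Ighd go with them, so B cells are not excluded. The levels of the neighbours argue against reads of neighbouring genes, and expression by the macrophages stays open, as untested.

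The tests of low alveolar macrophage transcripts in interstitial libraries were chosen after the values were seen as well. Of 27 genes at least 100-fold higher in AM, 26 were higher in IM1 than in IM3, with median levels of 0.554%, 0.305% and 0.145% of AM in IM1, IM2 and IM3. AM cells or RNA, or reads exchanged between pooled libraries, would as the only source give all genes the same share, but Siglecf was at 0.218%, 0.328% and 0.768% and Chil3 at 0.361%, 0.126% and 0.0214%; the 90th percentile of the shares was at least 7.9 times the 10th in each IM1 library, and the gate removed cells with Siglec F, so each is unlikely as the only source. Exchanged reads might still give part of the level, and the highest share of 10 interstitial genes in AM was 0.164 of the lowest share of 10 alveolar genes in IM1. An earlier form on median shares (0.0416% in AM) would have excluded exchange and was replaced because its value lay within the spread between libraries, and exchange as part of the level cannot be told apart from low expression.

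Regrouping of the libraries was planned. For interstitial against AM the real grouping was 1 of 100, the others being drawn at random, with 8300 genes against 0 at most for the others drawn. Here and for the pairs below, every other split mixes populations within a group, which widens the spread there. Low counts in the other splits were therefore to be expected, and the regrouping cannot decide on a chance split. For 3 libraries against 3 the real grouping was 1 of 10, too few splits for a share under 0.05, with 6969, 8746 and 8670 genes for IM1, IM2 and IM3 against AM, 71 for IM1 against IM2, 2268 for IM1 against IM3 and 2143 for IM2 against IM3. Any other split gave 0 at most, including the 3 splits that also part every same-letter pair.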
